A study of Mus musculus with 2 samples.

How the data were processed

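Polyadenylated RNA of mouse retina was sequenced after light exposure, in 1 library labelled wild type for Otud7b and 1 labelled homozygous knockout. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The authors deposited gene-level FPKM values, fragments normalized for transcript length and sequencing depth, with 1 value per gene symbol and library. Per the submitters' processing notes, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, Cuffdiff 2.2.1 and the mm10 build were used. The gene annotation, the strand setting, the treatment of reads with several matches and the library-size method are not given in the sources used here. Reads of near-identical copies and of overlapping genes could therefore be divided between them, and values of histone, ribosomal protein, glutathione transferase and hemoglobin genes are uncertain for this reason.

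FPKM values are not counts, so no count model was run. With 1 library per genotype there was no test, no standard error and no leave-one-out. Log2 ratios were computed as the library labelled knockout over the library labelled wild type after adding 1 FPKM, for 13260 genes with a mean of at least 1 FPKM over both libraries. Genes were counted as different by a fixed rule of size, at least 2-fold on that scale, and list members at 1.5-fold. A log2 ratio on that scale understates the difference of low genes, so plain FPKM values are given beside it.

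Gene lists for retinal cell types, inflammation, stress, metabolism and neighbouring tissues were fixed before the data were examined, 40 in all. The 34 with at least 5 measured members were scored by the percentile of their median log2 ratio among 10000 random lists. Random lists had the same size and were matched in 20 bins of mean expression. The percentile describes these libraries and is not a p-value. A list was said to stand apart outside the central 95%. The named genes were Otud7b, the 10 highest and 10 lowest log2 ratios without small RNA, predicted, unnamed and pseudogene symbols, and up to 4 members per list with the largest difference in size. Added to these, whatever their values, were Opn1sw, Opn1mw, Arr3, Gnat2, Gnat1, Gfap, Aif1, Nfkbia and Tnfaip3. Some genes that these rules name are not reported here. Other genes named were chosen after their values were seen, and the closing part says so.

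Low values moved in steps of whole fragments. In 328 genes with low values the ratio between the libraries was 0.983, to within 0.1%, which is what 1 fragment in the library labelled knockout was worth relative to the other. With transcript lengths less 210 bases and a depth of 8700000 fragments, 71.5% of 1446 low values in the library labelled wild type lay within 0.1 of a whole number of fragments. In the library labelled knockout it was 72.1% of 1415, and 20% is expected by chance. The estimate rests on 180 genes with a single transcript, 52 of which lay within 1% of 1 fragment. From the estimated fragments, exact Clopper-Pearson 95% intervals of the ratio were computed. They cover counting error only, not differences between animals or preparations, and their use was decided after seeing the data. Positions came from the RefSeq annotation of GRCm38, the assembly of the mm10 build, for 24228 symbols, and the median annotated transcript length from GENCODE for 23971.

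The rules were tested on simulated data before use. The simulated comparison held transcripts of at least 500 bases and counting error only. Its shares of unchanged genes and lists called therefore leave out short transcripts and variation between animals or preparations. In it, the 2-fold rule called 0% of 50 genes changed 1.5-fold and 30% of 50 changed 2-fold. It called 93.9% of 49 changed 3-fold, 98.0% of 49 changed 4-fold, and 0.0391% of 12801 unchanged genes. The 1.5-fold rule called 42%, 94%, 100% and 98.0% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, and 0.797% of unchanged genes. A simulated list of 20 genes shifted by 1.15-fold was placed at percentile 100, and 6.5% of 200 unchanged lists fell outside the central 95%.

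Alternatives covered the pseudocount (0.1 and 5 FPKM), the filter on low values, 4 rescalings of the libraries, removal of trends with expression or length, the threshold, the matching of random lists and the mean in place of the median. Leaving out short transcripts or the genes of chromosome 3 was added after seeing the data. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.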

Results

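Messenger RNA was profiled in the retina of mice after exposure to light, in 1 library labelled wild type for Otud7b and 1 labelled homozygous knockout. Otud7b encodes a deubiquitinase, an enzyme that removes ubiquitin from other proteins, and the study's title links it to the degeneration of cone photoreceptors. The comparison asks how the retinal transcriptome after light exposure differed between these genotypes. The labels give neither the light dose, the age of the animals nor how many retinas entered a library, and retina without light exposure was not analysed here. Each library holds a value in FPKM, fragments normalized for transcript length and sequencing depth, for 24346 gene symbols, with sums of 383507 FPKM in the library labelled wild type and 389995 in the library labelled knockout. The median was 1.96 and 2.01 FPKM, and 7578 and 7559 symbols were listed at 0. From the steps between low values, the depth was estimated at about 8700000 and 8846842 fragments, at which 1 fragment on a transcript of 2000 bases is worth 0.0642 and 0.0631 FPKM. With 1 library per genotype there was no replicate check and no test. Every difference below is between these libraries, and the 95% intervals cover counting error only and rest on the estimated depth. Several values are given without their interval, and some of those intervals include a ratio of 1. Log2 ratios are on the scale of FPKM + 1, which understates the differences of low genes.

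Otud7b itself (chromosome 3, 96104504 to 96161129, GRCm38) was not lower in the library labelled knockout. It stood at 28.4 FPKM there and at 27.5 FPKM in the library labelled wild type, a log2 ratio of 0.05 and a plain ratio of 1.04 (95% counting interval 0.971 to 1.10). These values rest on an estimated 1970 and 1872 fragments. A value per gene pools all exons, so it does not check an allele that lacks only part of the transcript, and the sources used here do not say how the allele was made. Because this value does not bear out the label, the libraries are named by their labels throughout, and every direction given below rests on those labels.

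Cone photoreceptor transcripts were at similar levels in both libraries. Of 15 cone genes, 0 differed by at least 1.5-fold, and the list had a median log2 ratio of 0.05, at percentile 93.5 of random gene lists matched on expression. The short-wavelength cone opsin Opn1sw was at 216 FPKM in the library labelled wild type and 228 in the library labelled knockout (ratio 1.06, 1.01 to 1.11), and the medium-wavelength opsin Opn1mw at 86.7 and 95.8 (ratio 1.11, 1.002 to 1.22). Cone arrestin Arr3 was at 89.6 and 90.2 FPKM (ratio 1.01, 0.917 to 1.10), and the cone transducin Gnat2, which lies on chromosome 3, at 88.2 and 92.0 (ratio 1.04, 0.970 to 1.12). The largest cone differences in size were in the channel subunit Cngb3, at 3.34 and 4.59 FPKM, and the nuclear receptor Rxrg, at 4.22 and 3.12. The phosphodiesterase subunit Pde6h was at 139 and 156 FPKM.

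Rod transcripts were slightly higher in the library labelled knockout, by about 1.04-fold at the median, and the cone list by about 1.03-fold. Random lists matched to the cone genes spread more widely (central 95% -0.0601 to 0.0604, against -0.0353 to 0.0382 for the rod list). The percentiles therefore do not show a shift particular to rods. The 21 rod genes had a median log2 ratio of 0.05, with 19 above 0 and 0 past 1.5-fold, at percentile 99.6 of matched random lists. Rod transducin Gnat1 was at 3660 FPKM in the library labelled wild type and 3917 in the library labelled knockout (ratio 1.07, 1.06 to 1.08). The transcription factor Esrrb was at 89.6 and 98.5 FPKM and Samd7, on chromosome 3, at 60.9 and 68.0. The potassium channel Kcnj14 went the other way, at 145 and 133 FPKM. Scored by its mean instead of its median, the rod list was at percentile 77.7, and without matching on expression its median was at percentile 93.6, both inside the central 95% of random lists. The 29 genes shared by rods and cones had a median log2 ratio of 0.03 (percentile 93.9), with Guca1b, an activator of guanylate cyclase, at 269 and 296 FPKM.

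Bipolar cell genes lay on both sides of 0. The 17 genes had a median log2 ratio of -0.05, at percentile 2.40, with 8 above and 9 below 0 and 0 past 1.5-fold. Gng13 was at 264 FPKM in the library labelled wild type and 231 in the library labelled knockout, and Prkca, a marker of rod bipolar cells, at 50.1 and 54.4. This list lay inside the central 95% of random lists under 6 alternatives, among them its mean (percentile 16.9) and the list without genes of chromosome 3 (percentile 17.8). Of the other inner retinal neurons, the 14 amacrine genes had a median of -0.04 (percentile 9.65), with Th at 2.45 and 3.36 FPKM and Dab1 at 17.3 and 13.6. The 8 horizontal cell genes had a median of -0.07 (percentile 11.7), with Onecut1 at 2.07 and 1.33 FPKM. The 15 ganglion cell genes were centred on 0.00 (percentile 49.5) and the 16 ribbon synapse genes on 0.01 (percentile 60.0), where Rims1 was at 29.9 and 24.6 FPKM.

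**Figure D1:**
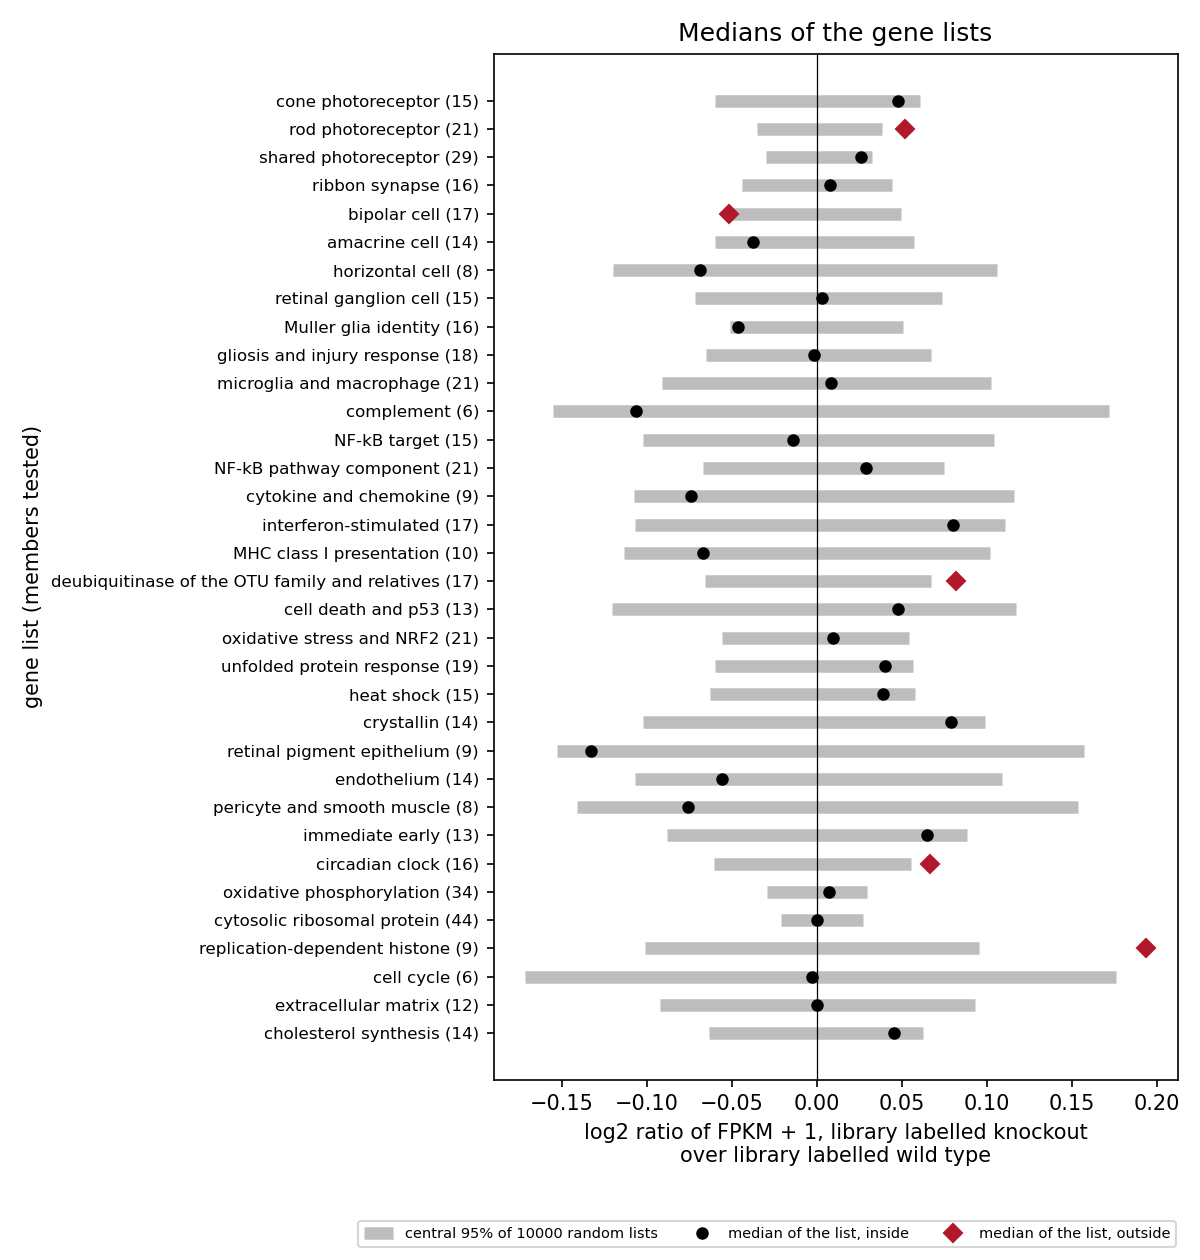
Median log2 ratio (library labelled knockout over library labelled wild type, FPKM + 1) of each scored gene list (points), with the central 95% of medians of 10000 random lists of the same size matched on mean expression (bars). Of 34 lists, 4 lie above and 1 below that range, and 1.7 would be expected outside it for lists of unrelated genes.

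Gliosis, the reaction of glia to injury, showed 2 genes that were at least 1.5-fold higher in the library labelled knockout and 0 that were lower by as much. Lcn2, an iron-binding acute-phase protein of reactive glia, was at 5.93 FPKM in the library labelled wild type and 17.1 in the library labelled knockout (ratio 2.89, 1.97 to 4.34). Timp1, an inhibitor of matrix proteases, was at 1.71 and 3.69 FPKM, with an interval of 0.967 to 5.22 around its ratio of 2.16. Ednrb, at 2.12 and 3.15 FPKM (ratio 1.49, 1.09 to 2.04), did not pass 1.5-fold. Gfap, the intermediate filament that marks reactive Muller glia and astrocytes, was at 45.0 and 43.6 FPKM (ratio 0.968, 0.883 to 1.06). The 18 measured gliosis genes divided evenly, with 9 above and 9 below 0, a median of 0.00 (percentile 45.8) and a mean of 0.13, which has the other sign. Scored by the mean, which Lcn2 weighs on, the list was at percentile 97.54. The 16 genes of Muller glia identity had a median of -0.05 (percentile 3.91), with 12 below 0. Their largest difference was in the transcription factor Sox9, at 3.53 and 5.34 FPKM.

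Microglial and macrophage transcripts showed no common direction. Of 27 genes, 21 reached a mean of 1 FPKM, with 11 above and 10 below 0 and a median of 0.01 (percentile 53.7). Ly86 (1.32 and 3.17 FPKM; ratio 2.40, 1.14 to 5.46) and the Fc receptor subunit Fcer1g (1.29 and 3.05 FPKM; ratio 2.36, 0.798 to 8.21) were more than 1.5-fold higher in the library labelled knockout. Lgals3 was lower there, at 4.83 and 2.91 FPKM (ratio 0.602, 0.362 to 0.984). Tyrobp was at 11.7 and 8.34 FPKM, with an interval of 0.412 to 1.21 around its ratio of 0.710. Aif1, the microglial marker also called IBA1, was at 1.22 and 0.683 FPKM, and its ratio of 0.562 had an interval of 0.116 to 2.28, so no difference was detectable at this depth. The 6 measured complement genes had a median of -0.11 (percentile 7.86) and a mean of 0.07. Their mean was raised by Cfi, a complement inhibitor on chromosome 3, at 0.370 and 1.94 FPKM.

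The measured targets of NF-kB, the inflammatory transcription factor, were similar as a group. Only 15 of the 34 target genes reached a mean of 1 FPKM, and the rest, most of the listed cytokines among them, were not scored. The 15 genes had a median log2 ratio of -0.01 (percentile 39.8) and a mean of 0.03. The inhibitor Nfkbia was at 14.5 FPKM in the library labelled wild type and 13.5 in the library labelled knockout (ratio 0.932, 0.748 to 1.16). The deubiquitinase Tnfaip3, also called A20, was at 65.8 and 68.8 FPKM (ratio 1.05, 0.988 to 1.11). Relb, a subunit of the noncanonical pathway, passed 1.5-fold, at 0.579 and 1.77 FPKM (ratio 3.05, 1.46 to 6.96). Rel, another subunit, was at 2.13 and 1.43 FPKM. The 21 measured components of the pathway had a median of 0.03 (percentile 73.5) and 0 past 1.5-fold, with Traf2 at 8.51 and 6.85 FPKM. Of 9 measured cytokines and chemokines, Ccl12 was more than 1.5-fold lower in the library labelled knockout, at 2.85 and 1.05 FPKM (ratio 0.369, 0.0641 to 1.52), and the list's median was -0.07 (percentile 8.31). The 17 interferon-stimulated genes had a median of 0.08 (percentile 92.5, but 99.8 among genes with a mean of at least 5 FPKM and 97.9 without matching on expression), with Isg15 at 1.97 times the level of the other library in the library labelled knockout (0.686 to 6.36). The 10 genes of MHC class I presentation had a median of -0.07 (percentile 12.1) and a mean of 0.03, with the immunoproteasome subunit Psmb9 at 1.16 and 3.05 FPKM.

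Across the transcriptome the libraries were close. Over 13260 genes with a mean of at least 1 FPKM, the Pearson correlation of log2 values was 0.975 and the Spearman correlation 0.985, across genes, which are not independent replicates. The median log2 ratio was 0.00. In the central 90% of genes the fold ran from 0.906 to 1.09 at a mean of 100 FPKM or more, and from 0.719 to 1.48 between 1 and 2 FPKM. At least 2-fold differences were counted in 67 genes, 39 higher and 28 lower in the library labelled knockout. Of these, 20 were small RNA genes and 17 predicted or unnamed genes, and 24 were listed at 0 in 1 library. The total was 145 with a pseudocount of 0.1 FPKM and 26 with 5 FPKM. With transcripts under 500 bases left out, a choice made after seeing the data, 24 were higher and 11 lower. Of these 35 genes, 10 lay on chromosome 3, which holds 634 of the 13028 genes kept. Leaving out the genes of chromosome 3 instead, also chosen after seeing the data, gave 30 higher and 25 lower.

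The named genes with the highest ratios included several low transcripts. The secreted glycoprotein Olfml3 (chromosome 3, 103735394 to 103738001) was at 2.79 FPKM in the library labelled wild type and 9.64 in the library labelled knockout (ratio 3.46, 2.65 to 4.56). Prok1, a secreted prokineticin (chromosome 3, 107231916 to 107239707), was at 0.575 and 3.39 FPKM (ratio 5.90, 2.85 to 13.9). The glutathione transferase Gstm6 (chromosome 3, 107938847 to 107953641), one of a cluster of similar genes, was at 0.245 and 2.41 FPKM (ratio 9.83, 2.39 to 86.3). Tmsb15l was at 1.71 and 7.59 FPKM (ratio 4.44, 2.13 to 10.4), Cstad at 0.190 and 2.25, and Riiad1, also on chromosome 3, at 0.832 and 3.27. Lcn2 belonged to this group too. Rpl26, Ubald2 and Lgals6 were listed at 0 in the library labelled wild type and at 7.08, 3.15 and 2.102 FPKM in the other. Rpl26 encodes a ribosomal protein that every cell uses, so an exact 0 can be a failed estimate, and no fold is given for genes at 0.

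The 10 named genes with the lowest ratios included 3 histone genes and 1 ribosomal protein gene, kinds that have close copies elsewhere in the genome. The ribosomal protein gene Rpl30 was at 24.2 FPKM in the library labelled wild type and 7.03 in the library labelled knockout (ratio 0.290, 0.173 to 0.470). Hist2h2bb (chromosome 3, 96269700 to 96270192) was at 9.89 and 0.405 FPKM, with a transcript of 381 bases and an interval of 0.000129 to 0.378. Csrp3, a muscle LIM protein, was at 2.69 and 0.496 FPKM (ratio 0.184, 0.0341 to 0.648), and Hist1h1a at 2.38 and 0.425. Pet117 and Hist2h2ac (chromosome 3, 96220413 to 96220880) were listed at 0 in the library labelled knockout and at 6.26 and 2.26 FPKM in the other. Hist2h2bb and Hist2h2ac lie close to Otud7b, in the part of chromosome 3 taken up in the closing section. Rmrp, the RNA of a ribonuclease complex, was at 31.9 and 14.9 FPKM. Higd1b (2.43 and 0.651 FPKM), the secretin gene Sct (2.65 and 0.761) and the gonadotropin-releasing hormone gene Gnrh1 (4.85 and 1.83) were also lower. The counting intervals of these last 3 ratios reached above 1, to 1.49, 1.52 and 1.41.

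**Figure D2:**
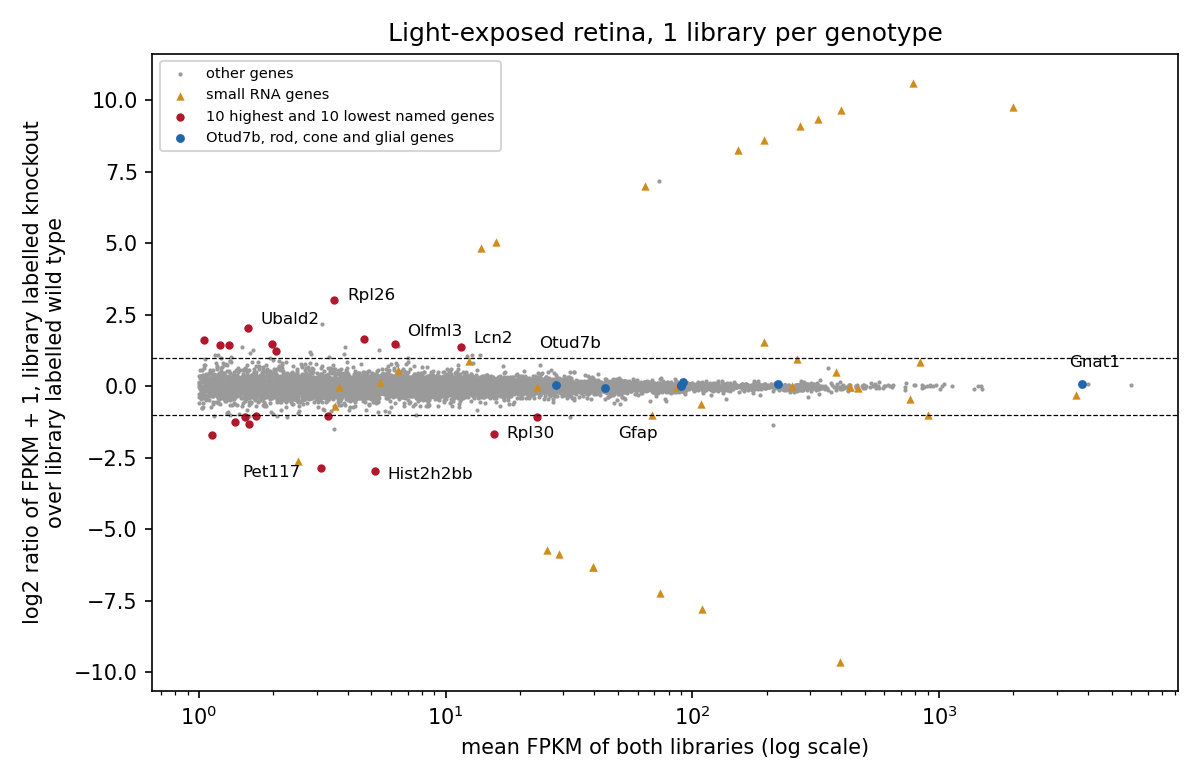
Log2 ratio of FPKM + 1 (library labelled knockout over library labelled wild type, vertical axis) against mean expression in FPKM (log axis) for the 13260 genes with a mean of at least 1 FPKM, with small RNA genes as triangles, the 10 highest and 10 lowest named genes in red, Otud7b with rod, cone and glial genes in blue, and dashed lines at a 2-fold difference. Apart from small RNA genes the spread narrows as expression rises, and 67 genes lie at or beyond the dashed lines.

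Beyond the rod list, 3 more lists stood above the central 95% of random lists. The 17 deubiquitinases of the OTU family and of other families had a median of 0.08 (percentile 99.0), with 14 above 0 and 0 past 1.5-fold. Cyld, Usp4, Usp7 and Usp21, which are not OTU enzymes, had log2 ratios of 0.10 to 0.12, all above that median. The OTU genes alone were not scored, so the percentile does not describe that family. Otulin, which cleaves linear ubiquitin chains, was at 8.73 and 10.4 FPKM, and Otud7a, the closest relative of Otud7b, at 5.76 and 5.21. The 16 circadian clock genes had a median of 0.07 (percentile 98.9), with 13 above 0. Per1 was at 28.2 and 33.8 FPKM (ratio 1.20, 1.11 to 1.30), Cry1 at 15.8 and 17.8, and Ciart, on chromosome 3, at 7.48 and 9.84. Scored by the mean, both lists were inside the range, at percentiles 93.1 and 96.5, and without matching on expression the clock list was inside it at percentile 96.2. The 9 replication-dependent histone genes had a median of 0.19 (percentile 99.98) but a mean of -0.06 (percentile 18.3). Hist1h4i was at 8.52 and 19.1 FPKM and Hist2h4, on chromosome 3 close to Otud7b, at 4.73 and 2.66. Of 34 lists scored, 5 lay outside the range, and 1.7 would be expected there for lists of unrelated genes. Genes of one cell type or pathway can vary together between any 2 samples, so the comparison with 1.7 does not show an excess over chance.

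Among activity and stress genes, the orphan nuclear receptor Nr4a3, an immediate early gene, was higher in the library labelled knockout at 0.636 and 2.04 FPKM (ratio 3.20, 2.12 to 4.98). The mRNA-decay factor Zfp36 was at 2.59 and 4.37 FPKM and Egr1 at 24.4 and 21.0, and the 13 immediate early genes had a median of 0.06 (percentile 92.9) but lay above the central 95% when scored by the mean (98.2), with a pseudocount of 0.1 FPKM (98.3) or with no filter on low values (98.6). No member passed 1.5-fold among 13 cell death genes (median 0.05, percentile 80.5), 21 genes of oxidative stress (0.01, 63.0), 19 of the unfolded protein response (0.04, 90.9) or 15 of heat shock (0.04, 91.4). In these lists Bax was at 33.8 and 27.1 FPKM, Gclm, on chromosome 3, at 11.1 and 14.5, Atf3 at 6.90 and 9.03, and Hspe1 at 52.8 and 42.4. Medians were 0.01 for 34 genes of oxidative phosphorylation (percentile 66.0), 0.00 for 44 ribosomal protein genes (38.8), 0.00 for 6 cell cycle genes (50.4), 0.00 for 12 matrix genes (47.8) and 0.05 for 14 cholesterol synthesis genes (92.6). Ndufb3 was at 66.8 and 82.1 FPKM, Mcm4 at 4.04 and 5.55, and Col6a1 at 44.6 and 37.0.

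Markers of tissue next to the retina were mostly low. Of 19 genes of the retinal pigment epithelium, 9 were measured, with 8 below 0 and a median of -0.13 (percentile 4.30, and 0.99 without matching on expression, which is outside the central 95%), and Ttr was at 8.66 and 5.60 FPKM. The 14 measured crystallins, proteins of the lens that retina also makes, had a median of 0.08 (percentile 94.3), with Cryba4 at 2.35 and 4.62 FPKM and Cryge at 6.44 and 3.96. Of 7 other lens genes and 6 of surface epithelium, 0 reached a mean of 1 FPKM. The 14 endothelial genes had a median of -0.06 (percentile 14.2), with Egfl7 at 4.12 and 6.88 FPKM, and the 8 pericyte genes -0.08 (13.3), with Tagln at 3.01 and 1.73. The 4 measured astrocyte genes were all above 0, with S100b at 3.81 and 5.69 FPKM. Skeletal muscle was represented by Acta1 at 1.36 and 0.891 FPKM and Mylpf at 3.18 and 2.71, and red blood cells by Hbb-b1 at 9.08 and 16.8 and Hba-a1 at 12.3 and 15.99. Of the sex-linked genes, Xist was at 258 and 267 FPKM, and Ddx3y and the other 3 Y-linked genes were listed at 0 in both libraries.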

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

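Leaving out short transcripts or the genes of chromosome 3 was decided after seeing the data, and all other settings before. The ratio of Otud7b and the correlation of the libraries held under every alternative run for them. The number of genes differing 2-fold stayed within 1.5 times of 67 under all 4 rescalings, both trend removals, no filter on low values and without chromosome 3. It was 145 with a pseudocount of 0.1 FPKM (84 higher, 61 lower), 26 with 5 FPKM (14 and 12), 32 at a mean of at least 5 FPKM (19 and 13), 35 without transcripts under 500 bases (24 and 11), and 248 at 1.5-fold (145 and 103). A smaller pseudocount widens the ratios of low genes by construction, and the higher minimum leaves 10178 genes. No rescaling moved the median log2 ratio of all genes beyond -0.02 to 0.01. List medians close to 0 took the other sign under at least 1 rescaling or trend removal for ribbon synapse, ganglion cell, gliosis, microglia, oxidative stress, oxidative phosphorylation, ribosomal protein, cell cycle and matrix genes. Scored by the mean, 2 lists in place of 5 stood apart, gliosis (percentile 97.54) and immediate early (98.2), and 0 of the original 5 did. Of these, the rod list was at 77.7, bipolar at 16.9, deubiquitinase at 93.1 and clock at 96.5, and the histone list turned to 18.3. Without matching on expression the rod list was at 93.6. The cause of these shifts was not tested. Over all lists and alternatives, 452 results kept their side of the central 95%, 11 moved inside it and 6 moved outside in the same direction. The other 2 are the gliosis and histone lists scored by the mean. Of the ratios of named genes, 1594 moved by no more than 1.5-fold, 33 moved further and 0 of those past 1.5-fold changed sign. The genes near Otud7b had a median absolute ratio inside the central 95% within 5 Mb (percentile 86.1) and above it within 10 Mb (99.84). No symbol was listed more than once, so leaving out repeated symbols was not run. No paired analysis was possible because each genotype has 1 library. Depth limits genes near 1 FPKM most, where an interval such as that of Aif1 spans 0.116 to 2.28.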

Other observations

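The main window around Otud7b was 5 Mb, scored by the median absolute log2 ratio of its genes, with 2 and 10 Mb as alternatives. These windows and this score were fixed before the data were examined. All other tests below, the shares past 1.5-fold among them, were chosen after the results were seen. The median absolute log2 ratio lay inside the central 95% of matched random lists within 2 Mb (percentile 86.9) and 5 Mb (percentile 86.1) and above it within 10 Mb (percentile 99.84). By the share past 1.5-fold, genes around Otud7b on chromosome 3 differed more often than genes elsewhere. Within 5 Mb, 11 of 92 genes (11.96%) differed at least 1.5-fold, against 1.80% of 13168 other genes. Within 2 Mb it was 8 of 81 genes and within 10 Mb 19 of 231. The differences went both ways: within 40 Mb, 17 genes were higher and 12 lower in the library labelled knockout. The collagen gene Col11a1 was at 4.74 FPKM in the library labelled wild type and 7.65 in the library labelled knockout (ratio 1.61, 95% counting interval 1.40 to 1.86). Arhgap29 was at 2.40 and 4.37 (ratio 1.82, 1.45 to 2.30), and the kinase gene Alpk1 at 5.51 and 3.08 (ratio 0.559, 0.443 to 0.702). The annexin partner S100a10 was at 21.1 and 32.1 FPKM, Etnppl at 1.88 and 4.85, and the small GTPase Rab13 at 9.90 and 5.83. These 6 genes were picked after their values were seen.

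The excess was concentrated on one part of the chromosome. Within 40 Mb of Otud7b, 29 of 431 genes (6.73%) differed at least 1.5-fold, against 2 of 202 (0.990%) on the rest of chromosome 3 and 168 of 12394 (1.36%) on other chromosomes, with transcripts under 500 bases left out. The excess reached less far below Otud7b in position than above it. All 29 lay from 10 Mb below Otud7b to 40 Mb above it (29 of 355 genes). In the 10 Mb below, 10 of 148 genes lay past 1.5-fold, and from 40 to 10 Mb below 0 of 76 did. Counting error is argued against: the number on chromosome 3 was 6.01 times that of simulated counting draws, and the next highest chromosome reached 4. Histone, Gstm, S100a and unnamed genes do not account for it either, since 5.33% still differed without them, against 1.12% elsewhere. Other genes of kinds with close copies were kept, such as the ribosomal protein gene Rpl34 (5.43 and 9.42 FPKM). Multicopy genes as a whole were therefore not tested. The 29 genes exceed the 11 of the highest of 436 windows of as many neighbouring genes on other chromosomes. These windows overlap heavily, so they are far fewer than 436 separate comparisons. A candidate explanation is sequence linked to the targeted allele, carried along from the strain in which it was made. Whether such sequence alters transcription or only the matching of reads, and whether loss of Otud7b itself acts on its neighbours, was not tested.

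Otud7b was not lower in the library labelled knockout. On chromosome 3, 4.89% of genes differed at least 1.5-fold, against 2.29% on the next highest chromosome. This argues against both libraries having one genotype only if the excess comes with the targeted allele, which was not tested. It does not show the genotype at Otud7b itself. With exchanged labels and an allele that lowers the transcript, Otud7b would be clearly higher in the library labelled knockout. The upper 95% counting limit of its ratio was 1.10, which argues against that pair of conditions. Correct labels with such an allele fare no better, since Otud7b was not lower. The value therefore does not tell exchanged labels from correct ones. An allele that leaves most of the transcript stays open: the log2 ratio was 0.0481, and values per gene do not show a missing exon. With such an allele Otud7b would not tell which library is which, so the labels remain unchecked.

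The 2-fold differences gathered in short transcripts. Of 40 genes with a transcript under 300 bases, 22 (55%) differed 2-fold, against 41 of 13129 longer ones (0.312%), as unstable FPKM of short transcripts may give, since few start positions remain for a fragment. Counting error alone is too small for the rest: 35 genes with transcripts of at least 500 bases differed 2-fold, against at most 15 in 100 simulated draws. Variation between animals, preparation and genotype cannot be separated in this remainder with 1 library each. Among near-identical copies, picked after their values were seen, Atp6v0c was at 278 and 433 FPKM and its pseudogene Atp6v0c-ps2 at 305 and 120. The ratio of their summed fragments was 1.252 (1.19 to 1.32), although in FPKM the pseudogene was lower by more than the gene was higher. Summed fragments weigh each copy by its annotated transcript length, and the interval does not cover an error in that length. For Eno1 (451 and 407 FPKM) and Eno1b (544 and 599) the ratio of summed fragments was 1.006 (0.983 to 1.03).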
